A study of Oryza sativa with 8 samples.

How the data were processed

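Total RNA of rice leaves was labelled with Cy3 by the authors and hybridised to 8 arrays of a custom 4X44K rice design, 1 array per file, on 3 slides. Slide 1 held both IR20 vegetative arrays and the IR20 grain-filling array of day 0, slide 2 the IR20 grain-filling array of day 8 and both Vandana vegetative arrays, and slide 3 both Vandana grain-filling arrays. The treatment text also names a collection after 2 days of recovery, which has no array in this series.

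Per the file headers, the deposited scanner files come from Agilent Feature Extraction 11.5.1.1. Their processed signal is an intensity on a linear scale, background-subtracted and detrended by the authors' software and not normalised between arrays. The mean spot signal and the local background in the deposited files are raw intensity values. Other deposited columns are flags per spot (0 or 1), such as saturated, well above background or not uniform. The deposited series matrix holds log2 values: each array's processed signal on the log2 scale minus 1 constant per array close to the array's 75th percentile. Between 99.8% and 99.9% of the probes fitted that description within 0.01, and how the authors made that table is not stated.

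Control spots and spots marked as not uniform or as outliers were left out, and spots of a probe were averaged. Of 42418 probes 42363 had a value on all 8 arrays, and 41834 of the probes carried a locus (29667 loci). The reference table of gene symbols matched 0 of these loci, so genes are named by locus and by the description in the array files. The values analysed are log2 of the processed signal minus the array's 75th percentile. Probes well above background on at least 2 of the 8 arrays were tested, 34211 probes of 23454 genes. For gene lists and named genes each gene is represented by the probe with the highest mean signal. The 75th percentile of the processed signal was 2269.5, 2030.4, 1576.0 and 2814.6 in IR20 (vegetative day 0 and 8, grain filling day 0 and 8) and 1809.4, 1194.1, 303.6 and 1755.4 in Vandana. Genes at the top of the scanner's range numbered 224, 218, 239 and 334 on the IR20 arrays and 278, 224, 32 and 106 on the Vandana arrays.

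The stress, interaction, variety and stage comparisons were fitted with limma 3.58.1 in R 4.3.3 (linear model with moderated variance, two-sided, Benjamini-Hochberg over probes, threshold 0.05). The stress response was day 8 against day 0 with the variety and stage combination as a block. Its dependence on variety and on stage was tested by an interaction term, and variety and stage themselves with the matched combinations as blocks. With 1 array per combination the fits have 3 residual degrees of freedom, or 2 for an interaction. A response that differs between pairs therefore enters the error. On simulated data of the same size and spread, 200 of 34211 probes were changed by 4-, 16- or 64-fold. The stress fit recovered 0, 64 and 160 of them, the variety fit 0, 0 and 138, the stage fit 0, 0 and 137 and the interaction fits 0 at each size.

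The gene lists, by locus or by words of the description, the comparisons, the rule for named genes and the alternatives not named as later were fixed before the data were examined. The 26 lists are LEA proteins and dehydrins, ABA synthesis and turnover, ABA signalling kinases, protein phosphatases 2C, drought-associated transcription factors, heat shock proteins, compatible solute synthesis, antioxidant enzymes, aquaporins, light harvesting and photosystems, Calvin cycle, chlorophyll synthesis, chlorophyll breakdown and leaf senescence, nitrogen assimilation, sucrose and starch metabolism, cytosolic ribosomal proteins, cell division and DNA replication, cell wall expansion, jasmonate synthesis and response, pathogenesis-related proteins, circadian clock, flowering time and floral identity, seed storage, root, anther and pollen, and reference genes. Loci and word matches whose description in the array files contradicted the list were left out by that description alone. No gene tested stands in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation. Members were counted over all genes tested and adjusted over the list alone. The adjustment over the list alone was made separately in each list and comparison and does not cover the others, so some members can pass by chance. On simulated data, 3 of 26 lists of 30 genes were shifted by 1 log2 unit. Camera called these 3 and 0 others in each comparison with the preset correlation. With an estimated correlation it called 3 for variety and 0 for the other comparisons. The simulated probes varied independently of each other, so this simulation cannot show false calls for lists whose genes vary together. In single pairs a list is described by the percentile of its median among 10000 random lists matched on mean signal.

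The rule for named genes took, for stress, variety and stage, the 10 largest differences in each direction among probes that passed and went the same way in all 4 pairs, with exactly 1 described gene and a signal well above background on all 4 arrays of the brighter side, filled by smallest unadjusted p where fewer passed. None passed, so all were filled in this way. It took the 3 smallest p values in each direction for the interactions, since none passed, the 5 largest in each direction within each pair, and in each list the 2 members with the largest differences and a few key loci. Members that passed over the list alone and probes of a named gene are added where a count refers to them.

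Alternatives tried were normexp background correction (offset 50), quantile normalization, median centring, the series matrix values, no filter or a filter on all 8 arrays, trend and robust moderation, a linear model without moderation, an additive fit, slide as a fixed or random block, both interactions in 1 fit, the mean of all probes of a gene, and each pair left out in turn. Probes and genes below the scanner ceiling, lists without exclusions, list medians in each pair under each scaling, and dim signals raised to the lowest signal well above background on their array (floored), were added after seeing the data. Random lists and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out.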

Results

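Gene expression was measured in rice leaves on 8 single-colour oligonucleotide arrays, 1 for each combination of variety, developmental stage and time. The varieties were IR20, which the labels call susceptible to soil water stress, and Vandana, which they call tolerant. One label field of the IR20 arrays reads IR2, while their titles and descriptions read IR20. Leaves were taken at the vegetative and the grain-filling stage, before stress (day 0) and after 8 days of soil water stress. No array holds unstressed leaves of day 8. What is called the stress response below is day 8 minus day 0, in which stress and 8 days of ageing cannot be told apart. No combination has a replicate among these arrays. The title of the series calls them set 2, and whether another set holds replicates is not known. The 4 pairs of arrays that share variety and stage therefore serve as replicates of the stress response. The precision of every value below is limited by this number of arrays. Between 64.8% and 75.8% of the spots on an array lay well above background, and the 75th percentile of the signal ran from 1194.1 to 2814.6 on 7 arrays and was 303.6 on the Vandana grain-filling array of day 0. Differences are given on the log2 scale as day 8 minus day 0, Vandana minus IR20, or grain filling minus vegetative, with the standard error (SE) of the fit and n, the number of pairs. "At least" before a fold means that the lower side was not well above background on any of its arrays and was counted at its own signal or at the lowest signal well above background on that array, whichever was higher. A difference that rests on dim signals, those not well above background, depends on the background of the array. "Floored" marks a difference with each dim signal raised to that lowest signal, a setting chosen after seeing the data. Genes carry the locus name and description of the array's annotation. Genomic positions and a genome build are not given in the files.

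The first question is how leaf transcripts differed after 8 days of water stress in both varieties and at both stages. Genes for late embryogenesis abundant (LEA) proteins and dehydrins, hydrophilic proteins that accumulate in drying plant tissue, rose as a list by camera with a preset correlation, with a median of 1.09 over 23 genes, and 0.15 without the IR20 vegetative pair (adjusted p = 0.986 with an estimated correlation). The group 3 LEA gene Os05g0542500 rose by 7.71 (SE 1.70, n = 4, floored 6.84), at least 114-fold, and the dehydrin gene RAB 16B (Os11g0454200) rose by 6.67 (SE 1.65, n = 4, floored 6.62), both at a limma adjusted p of 0.0439 over the list alone (0.0527 floored, so these calls ended). Genes for cytosolic ribosomal proteins rose together by a smaller amount in the same test, with a median of 0.78 over 149 genes. Lists for cell wall expansion (median -0.91, 54 genes) and for jasmonate synthesis and response (median -0.93, 19 genes) fell. For these 3 lists too the adjusted p was 0.986 with an estimated correlation.

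Adjusted over the list alone, 6 of the 23 LEA and dehydrin genes rose and 0 fell, against 0 over all genes tested by limma, where 7 were higher and 0 lower at an unadjusted p under 0.05. The floored values gave 0 of 23 over the list alone, with adjusted p from 0.0527 to 0.0725 for the 6 genes. The other 4 were Dehydrin 9 (Os11g0451700, 5.30, SE 1.35, floored 4.72), Dehydrin RAB 16D (Os11g0453900, 6.41, SE 1.68, floored 5.57) and the dehydrin family genes Os11g0454000 (4.17, SE 0.80, floored 3.7) and Os11g0454300 (5.82, SE 1.36, floored 5.82), each with n = 4, and all 6 genes were higher in 4 of 4 pairs. Dehydrin 9 and RAB 16D differed by only 0.49 in the Vandana vegetative pair, where the scaling of the arrays alone added 0.60. Their unscaled signal was therefore not higher at day 8, and a rise in that pair is not shown for either gene. RAB 16D was dim on all 4 arrays of day 0. The list's median was 3.73 in the IR20 vegetative pair, 1.14 in IR20 at grain filling, 0.48 in the Vandana vegetative pair and 0.38 in Vandana at grain filling. Against 10000 random lists of equally bright genes these medians stood at percentiles 100, 100, 89.0 and 98.9. Under normexp background correction the direction flipped at grain filling, with medians of -0.11 in IR20 and -0.71 in Vandana, the floored median was -0.09 in the Vandana vegetative pair and 2.78 in IR20, and the median over the 4 pairs was 0.69. The camera test gave an adjusted p of 0.00379 over the 26 lists, but adjusted p = 0.986 with an estimated correlation, and 0.0549 without the IR20 vegetative pair, where the median was 0.15.

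Of the 149 ribosomal protein genes, 73 were higher at day 8 in all 4 pairs and 0 were lower in all 4. Among all 23454 genes 2908 (12.4%) were higher in all 4, and chance alone would give 6.25%. The list's median was 0.94, 0.91 and 1.32 in the IR20 vegetative, IR20 grain-filling and Vandana vegetative pairs and 0.02 in Vandana at grain filling. Examples are the 40S protein S9 gene Os07g0628300 (2.13, SE 0.66, n = 4) and the 40S protein S15a gene Os02g0255200 (2.18, SE 0.96, n = 4), which did not pass on their own. The S15a value rests on Vandana at grain filling (5.74, against 0.47 to 1.34 in the other pairs). Camera gave an adjusted p of 7.24e-25, and adjusted p = 0.986 with an estimated correlation. No member passed over all genes or adjusted over the list alone with limma (counts of 0), where 45 were higher and 0 lower at an unadjusted p under 0.05.

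In the cell wall list, which holds expansins and cellulose synthases, 12 of 54 genes were lower in all 4 pairs and 3 were higher in all 4. Among all genes 8.3% were lower and 12.4% higher in all 4, and chance alone would give 6.25% in each direction. The alpha-expansin OsEXPA13 (Os02g0267200) differed by -3.66 (SE 1.42, n = 4, floored -3.09), and a cellulose synthase family gene (Os07g0552800) by -3.31 (SE 0.62, n = 4), at least 5.43-fold lower. The median was -0.99 and -0.75 in the IR20 pairs, 0.36 in the Vandana vegetative pair (floored -0.09) and -2.02 in Vandana at grain filling. In that last pair the scaling of the arrays alone added -2.53, and the unscaled median was 0.51. Quantile normalization gave -0.82 there, so the size of that fall depends on the scaling. Without that pair the list's median was -0.44. Camera gave an adjusted p of 0.00194, and adjusted p = 0.986 with an estimated correlation. The jasmonate list includes lipoxygenases, which start the oxidation of fatty acids from which jasmonate is made. Its lipoxygenase genes Os08g0509100 (-3.52, SE 0.99, n = 4) and Os03g0738600 (-3.27, SE 1.14, n = 4, at least 6.20-fold lower) had the largest differences. The list's median was -1.22, -1.94 and -1.43 in 3 pairs and 0.13 in Vandana at grain filling, where it flipped to -0.55 under normexp background correction. Camera gave an adjusted p of 0.0315, and adjusted p = 0.986 with an estimated correlation. This call ended under quantile normalization (adjusted p = 0.0514), without the IR20 grain-filling pair (0.15, median -0.60) and without the Vandana vegetative pair (0.276). In both lists 0 members passed over all genes or adjusted over the list alone with limma. At an unadjusted p under 0.05, 3 cell wall genes were higher and 10 lower, and 0 jasmonate genes were higher and 3 lower.

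The list of light harvesting and photosystem genes also fell (median -0.64, 45 genes), at a camera adjusted p of 0.0459 and adjusted p = 0.986 with an estimated correlation. Its pair medians were 0.17, -0.86, 0.62 and -2.53 in the order IR20 vegetative, IR20 grain filling, Vandana vegetative and Vandana grain filling. Under quantile normalization they were 0.04, -0.20, 0.04 and -0.13. The gene for the photosystem II 10 kDa polypeptide (Os07g0147500) differed by -4.19 (SE 1.28, n = 4) with 1 array saturated, and Os07g0105600, a gene of the oxygen-evolving complex, by 1.69 (SE 0.46, n = 4). Adjusted over the list alone 0 members passed with limma, as over all genes, where 2 were higher and 1 lower at an unadjusted p under 0.05. Of the 45 genes 30 reached the top of the scanner's range on 1 or more arrays, and for the 15 below it on all 8 arrays the test pointed up (adjusted p = 0.93, median -0.03). The call also ended under quantile normalization (0.575, median -0.04), under median centring (0.053, median -0.63), with floored values (0.0703, median -0.64), without the IR20 grain-filling pair (0.418) and without the Vandana grain-filling pair (0.884, median -0.01), and without the Vandana vegetative pair the median was -1.05.

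**Figure D1:**
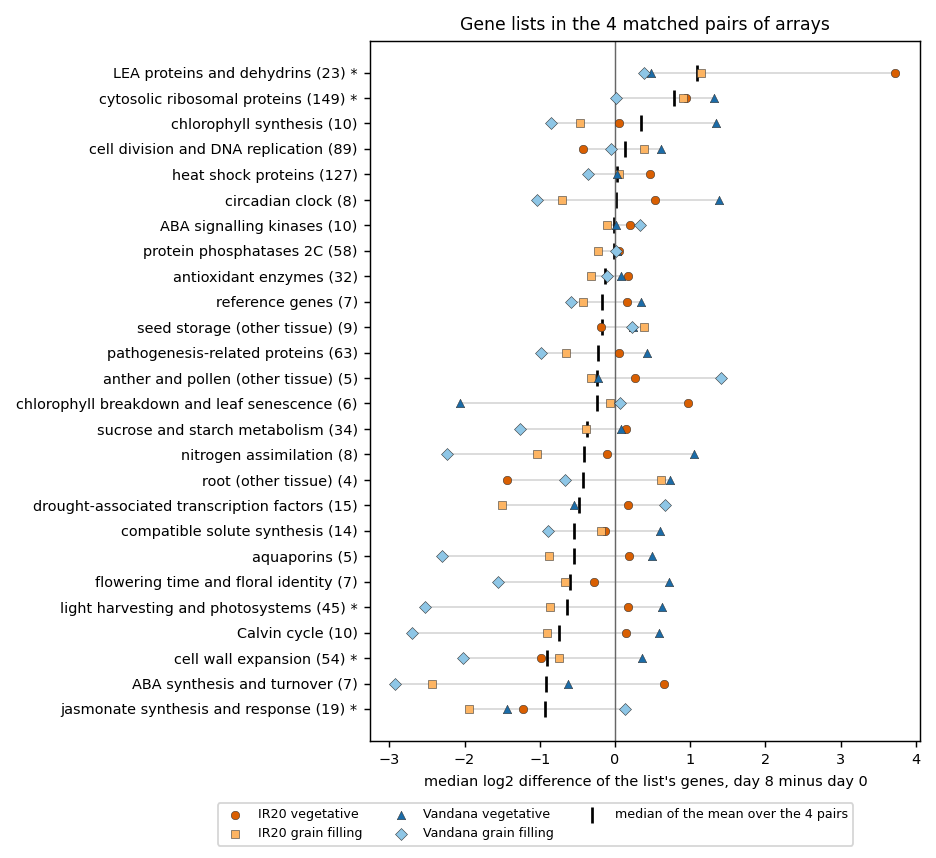
Median log2 difference (day 8 minus day 0) of the genes of each of the 26 lists in the 4 matched pairs of arrays, with the number of genes tested in parentheses and the median of the genes' means over the 4 pairs as a black bar. An asterisk marks a camera adjusted p under 0.05 with the preset correlation. The LEA and dehydrin list runs from 0.38 to 3.73 and the ribosomal list from 0.02 to 1.32, while light harvesting genes were at -2.53 in Vandana at grain filling (-0.13 under quantile normalization), and the LEA medians at grain filling flip under normexp background correction and the Vandana vegetative one when floored (-0.09).

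The other 21 lists did not pass for the stress response. Among lists on hormone and stress signalling, the median and camera adjusted p were -0.92 and 0.179 for ABA synthesis and turnover, -0.01 and 0.777 for ABA signalling kinases, -0.01 and 0.987 for protein phosphatases 2C, -0.47 and 0.814 for drought-associated transcription factors and 0.02 and 0.849 for heat shock proteins. They were -0.55 and 0.849 for compatible solute synthesis, -0.13 and 0.987 for antioxidant enzymes and -0.55 and 0.46 for aquaporins. In metabolism they were -0.75 and 0.0545 for the Calvin cycle, 0.34 and 0.849 for chlorophyll synthesis, -0.24 and 0.849 for chlorophyll breakdown and leaf senescence, -0.41 and 0.777 for nitrogen assimilation and -0.38 and 0.204 for sucrose and starch metabolism. They were 0.14 and 0.777 for cell division and DNA replication, -0.22 and 0.777 for pathogenesis-related proteins, 0.02 and 0.951 for the circadian clock and -0.59 and 0.777 for flowering time and floral identity. The 3 lists of other tissues gave -0.18 and 0.777 for seed storage (9 of 34 genes above background), -0.43 and 0.849 for root (4 of 7) and -0.23 and 0.987 for anther and pollen (5 of 6), and the reference genes gave -0.17 and 0.951. Median, mean and test differed in sign for 7 of these lists, namely ABA signalling kinases, protein phosphatases 2C, chlorophyll synthesis, the clock, seed storage, anther and pollen, and the reference genes.

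No single gene passed the test of the stress response over all genes. Of 34211 probes limma called 0 at an adjusted p under 0.05 (smallest 0.434), with 3653 at an unadjusted p under 0.05 (1866 higher, 1787 lower) where 1711 are expected by chance. A linear model without moderation also called 0. Without the IR20 grain-filling pair, which is also what slide as a fixed block removes, the unadjusted count was 1412 (532 higher, 880 lower), under the number expected, and lower probes outnumbered higher ones without any 1 of the 4 pairs. Quantile normalization gave 2516 higher and 1273 lower, and normexp background correction 2234 in all. By 2-fold or more in the same direction in all 4 pairs, 174 genes were higher and 243 lower. The gene with the smallest p among those lower was an isoflavone reductase homolog, Os01g0106300, at -5.02 (SE 0.51, n = 4), and its 7 probes ran from -5.31 to -4.81. CBL-interacting protein kinase 1 (Os07g0637000), a partner of calcium sensors, differed by -3.01 (SE 0.32, n = 4) and a terpene synthase-like gene (Os02g0121700) by -4.91 (SE 0.59, n = 4). Among those higher, a thioredoxin-related gene (Os02g0774100) differed by 3.33 (SE 0.34, n = 4), an aspartic peptidase (Os08g0508500) by 3.55 (SE 0.42, n = 4) and a putative rRNA pseudouridine synthase (Os03g0370500) by 2.68 (SE 0.35, n = 4). The other 14 named genes, chosen by smallest p, ran from 2.14 to 3.15 among those higher and from -3.60 to -2.35 among those lower. They include an L7Ae family ribosomal protein gene (Os07g0636400, 2.14), a mitochondrial carrier (Os03g0213800, 2.36), cytochromes P450 (Os06g0600400, -2.67, and Os12g0443000, -2.35) and the dioxygenase RAMOSUS1 (Os01g0566500, -2.42), an enzyme of strigolactone synthesis.

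Differences within single pairs are 1 array against 1 array, with no test. In IR20 vegetative leaves Os05g0542500 was higher by 13.66 (at least 6010-fold) and RAB 16B by 10.78 (1750-fold), while a histone H2B gene (Os01g0152700) differed by -10.96 (at least 893-fold lower). In IR20 at grain filling a lipid transfer domain gene (Os04g0415800) was higher by 13.24 (at least 5460-fold, with its day 8 value at the scanner ceiling), a nonspecific lipid transfer protein gene (Os05g0550600) by 10.69 (1650-fold) and RAB 16D by 9.87 (at least 468-fold), and a gene for a beta-glucosidase aggregating factor (Os12g0247700) differed by -11.75 (at least 1330-fold lower). In Vandana vegetative leaves a ribonuclease T2 gene (Os09g0537700) was higher by 12.19 (at least 1450-fold) and RAB 16B by 9.16 (at least 497-fold), and an MS5-like gene (Os03g0165900) differed by -10.63, with its day 0 value at the scanner ceiling. In Vandana at grain filling a DnaJ family heat shock gene (Os04g0675400) was higher by 9.31 (at least 276-fold) and CRT/DRE binding factor 1 (Os02g0677300), a factor of cold and drought responses, by 8.29 (312-fold). A tau class glutathione S-transferase gene (Os10g0529800) differed there by -13.30 (at least 4220-fold lower).

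The number of probes that differed by 2-fold or more was 5650 higher and 5859 lower in the IR20 vegetative pair and 6818 and 7069 in IR20 at grain filling. It was 4922 and 5072 in the Vandana vegetative pair and 6195 and 8412 in Vandana at grain filling. Under normexp background correction the share of these probes that were higher moved to 34.2%, 73.1% and 23% in the IR20 grain-filling, Vandana vegetative and Vandana grain-filling pairs. The median over all probes was 0.13, 0.07, 0.15 and -0.22 in the 4 pairs, and 0.13, -0.25, 0.53 and -0.75 with that correction, so each value above is relative to such a shift. Across probes, which are not independent replicates, the stress differences of the pairs correlated by 0.309 between the varieties at grain filling, 0.274 between stages in IR20, 0.194 between varieties in vegetative leaves and -0.199 between stages in Vandana. Pairs that share neither variety nor stage correlated by 0.198 (IR20 grain filling with Vandana vegetative) and 0.004 (IR20 vegetative with Vandana grain filling).

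The second question is whether the tolerant and the susceptible variety responded differently, with both stages as replicates. Only the IR20 grain-filling pair had its arrays on different slides, so a difference between slides enters the grain-filling replicate. The response of the LEA and dehydrin list was lower in Vandana than in IR20, with a median difference of -2.94 in vegetative leaves and -2.19 at grain filling (adjusted p = 0.995 with an estimated correlation). The group 3 LEA gene Os05g0542500 differed by -6.66 (SE 1.93, n = 2, floored -7.30) and RAB 16D (Os11g0453900) by -6.52 (SE 1.95, n = 2, floored -6.79), both dim on all 4 arrays of day 0. On day 8 the first had a scaled log2 signal of 4.46 and 0.89 in IR20 and -4.02 and -2.06 in Vandana. Of the list 12 of 23 members were lower by 2-fold or more at both stages, as were 1635 of all 23454 genes. By any amount 30.1% of all genes were lower at both, where chance alone would give 25%. Under quantile normalization the LEA medians were -2.68 and -0.34, and floored they were -2.87 and -2.19. With the preset correlation, and at adjusted p = 0.995 with an estimated correlation, chlorophyll synthesis was called up (median 1.69 in vegetative leaves, -0.30 at grain filling, 10 genes), as was cell division and DNA replication (0.86 and -0.33, 89 genes), whose grain-filling median flipped to 0.14 under quantile normalization. Examples are a magnesium chelatase subunit gene (Os03g0563300, 1.58, SE 1.28, n = 2) and a histone H2B.2 gene (Os05g0460500, 2.98, SE 0.84, n = 2, floored 1.57).

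Camera gave an adjusted p of 8.63e-05 for LEA proteins and dehydrins, 0.0309 for chlorophyll synthesis and 0.01 for cell division, and adjusted p = 0.995 with an estimated correlation for each. In these 3 lists 0 members passed over all genes or adjusted over the list alone with limma, where 7 LEA genes were lower, 0 chlorophyll genes differed and 1 cell division gene was higher at an unadjusted p under 0.05. Without the IR20 vegetative pair the adjusted p was 0.141 for LEA (median -0.50, against -2.33 with all pairs) and 0.929 for cell division (median -0.11, against 0.15), and the chlorophyll median was 1.27, against 0.72. Without the Vandana vegetative pair it was 0.0673 for LEA, 0.17 for cell division (median 0.07) and 0.94 for chlorophyll synthesis, whose direction turned (median -0.36). Without the IR20 grain-filling pair the medians of LEA and cell division were -4.07 and 0.67, and without the Vandana grain-filling pair those of chlorophyll and cell division were 2.31 and 0.55. The chlorophyll call also ended without the IR20 grain-filling pair (0.343), under quantile normalization (0.0826), in the 7 genes below the scanner ceiling (0.125, median 0.70) and without list exclusions (0.0712). Over all genes limma called 0 of 34211 probes (smallest adjusted p = 1), with 731 at an unadjusted p under 0.05 (224 higher, 507 lower) where 1711 are expected, and a linear model without moderation called 0. The unadjusted count was 3405 without the Vandana vegetative pair, 1550 without the Vandana grain-filling pair and 448 without the IR20 vegetative pair. It was 309 under normexp background correction (166 higher, 143 lower), and 345 in probes well above background on all 8 arrays. With both interactions in 1 fit 380 were higher and 854 lower, and under quantile normalization 398 were higher and 340 lower. The values with the smallest p were a glycosyltransferase (Os06g0220500, 6.61, SE 0.76, n = 2, floored 5.23) and a nitrate reductase (Os02g0770800, 7.29, SE 1.04, n = 2), the entry enzyme of nitrate assimilation, on the higher side. On the lower side were a jacalin-related lectin (Os01g0348900, -9.53, SE 0.97, n = 2), saturated on 2 of its brighter arrays and with 5 probes from -13.24 to -9.53, and a cytochrome P450 (Os01g0544200, -7.94, SE 1.08, n = 2, floored -6.83). The median of all probes in this comparison was -0.19.

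The third question is whether leaves responded differently at grain filling and at the vegetative stage, with both varieties as replicates. The IR20 arrays of grain filling lay on slide 1 (day 0) and slide 2 (day 8), so the response of that pair cannot be told apart from slide. The other pairs each shared a slide, and slide was not blocked for the interactions. Lists of nitrogen assimilation, ABA synthesis and turnover and the clock responded lower at grain filling in both varieties by camera with a preset correlation (adjusted p = 0.785 with an estimated correlation). The light harvesting and Calvin cycle lists were called lower in the same test (also adjusted p = 0.785 with an estimated correlation), but 30 of 45 and 10 of 10 of their genes reached the scanner ceiling. The median difference was -1.08 in IR20 and -3.18 in Vandana for light harvesting and photosystems (45 genes), -1.06 and -3.28 for the Calvin cycle (10 genes), -1.09 and -2.94 for nitrogen assimilation (8 genes) and -4.18 and -2.65 for ABA synthesis and turnover (7 genes). It was -1.06 and -2.51 for the circadian clock (8 genes), -0.60 and -3.23 for chlorophyll synthesis (10 genes), -1.01 and -2.84 for aquaporins (5 genes) and -0.07 and -1.31 for cytosolic ribosomal proteins (149 genes), for which the IR20 value flipped to 0.24 under quantile normalization. That normalization brought light harvesting to -0.21 and -0.22 and the Calvin cycle to -0.16 and -0.38. The labels give no hour of collection, so another time of day cannot be told apart from a response to stress in these lists. At grain filling the morning clock gene Os08g0157600 differed by -3.62 in IR20 and -5.73 in Vandana. The evening clock gene Os02g0618200 differed there by 2.03 and 0.72.

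Adjusted over the list alone, 4 of 7 genes of ABA synthesis and turnover responded lower at grain filling than in vegetative leaves, against 0 over all genes. They are zeaxanthin epoxidase (Os04g0448900, -2.69, SE 0.72), which acts early in ABA synthesis, a carotenoid cleavage gene (Os02g0704000, -3.60, SE 0.77) and the cytochrome P450 genes Os08g0472800 (-4.56, SE 1.08) and Os09g0457100 (-3.89, SE 0.67), listed as ABA 8'-hydroxylases, enzymes of ABA breakdown, each with n = 2. The same holds for 4 of 8 nitrogen genes, among them nitrate reductase NR1 (Os08g0468100, -4.15, SE 0.93, n = 2) and nitrite reductase (Os01g0357100, -3.77, SE 0.80, n = 2). It holds for 2 of 8 clock genes, a Myb domain gene (Os08g0157600, -6.49, SE 0.93, n = 2) and a response regulator (Os09g0532400, -2.95, SE 0.56, n = 2). It also holds for 2 of 10 chlorophyll genes, a Rieske domain gene (Os10g0567400, -5.48, SE 0.78, n = 2) and a magnesium chelatase family gene (Os03g0323200, -3.23, SE 0.68, n = 2). In the light harvesting, Calvin cycle, aquaporin and ribosomal lists 0 passed over the list alone with limma, with 15, 1, 2 and 1 members lower at an unadjusted p under 0.05. A chlorophyll a-b binding protein gene (Os01g0720500) differed by -5.38 (SE 0.81, n = 2) and phosphoribulokinase (Os02g0698000) by -2.90 (SE 0.58, n = 2), both at the scanner ceiling on some arrays.

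Camera gave adjusted p values of 2.03e-08 for light harvesting, 0.000394 for the Calvin cycle, 0.000911 for ribosomal proteins, 0.00627 for the clock, 0.0184 for chlorophyll synthesis, 0.0201 each for ABA synthesis and turnover and nitrogen assimilation and 0.0452 for aquaporins, and adjusted p = 0.785 with an estimated correlation for all 8. Under quantile normalization only the ABA and clock calls held, and the adjusted p was 0.0569 for light harvesting, 0.388 for the Calvin cycle, 0.0569 for chlorophyll synthesis (median -1.32, against -2.06), 0.173 for nitrogen (-0.61, against -2.01), 0.387 for ribosomal proteins (-0.19, against -0.74) and 0.28 for aquaporins (-0.67, against -1.89). All 10 Calvin cycle genes reached the scanner ceiling on 1 or more arrays. Their unscaled medians differed by -0.02, -0.07, -0.01 and -0.17 in the IR20 vegetative, IR20 grain-filling, Vandana vegetative and Vandana grain-filling pairs, while the scaling differed by 0.16, -0.84, 0.60 and -2.53, so the list's scaled difference follows the scaling of the arrays and is not a measured response. The unscaled medians of light harvesting were 0.01, -0.03, 0.02 and 0.00, and 3 of 5 aquaporins reached the ceiling. In the 15 light harvesting genes below the ceiling the adjusted p was 0.319 (median -1.19, against -2.08). In the 6 nitrogen genes below it the adjusted p was 0.106, while the median was -2.47, no smaller than the -2.01 of all 8.

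Leaving out a pair ended further calls. The ABA list had an adjusted p of 0.12 without the IR20 vegetative and 0.435 without the IR20 grain-filling pair, and chlorophyll synthesis 0.143 without the IR20 grain-filling and 0.337 without the Vandana vegetative pair. Without the Vandana vegetative pair the clock list had 0.0769, nitrogen 0.103 and ribosomal proteins 0.144, and without the Vandana grain-filling pair nitrogen had 0.12 and ribosomal proteins 0.166. The aquaporin list had 0.0513, 0.198 and 0.211 without the IR20 vegetative, Vandana vegetative and Vandana grain-filling pairs, 0.0629 with the mean of all probes of a gene and 0.0583 with floored values (median unchanged at -1.89). The chlorophyll median was -3.17 without the IR20 vegetative and -0.69 without the Vandana vegetative pair, and that of aquaporins -2.87 without the IR20 grain-filling pair. Without the Vandana grain-filling pair the medians were -1.30 for light harvesting, -1.26 for the Calvin cycle (-2.25 with all pairs) and -0.28 for ribosomal proteins. Over all genes limma called 0 probes (smallest adjusted p = 0.359), with 4196 at an unadjusted p under 0.05 (1381 higher, 2815 lower) where 1711 are expected, and a linear model without moderation called 0. Under normexp background correction 548 were higher and 6326 lower, and the count was 2563 without the Vandana vegetative, 2614 without the Vandana grain-filling and 6399 without the IR20 grain-filling pair. The values with the smallest p were a calcium-dependent protein kinase (Os08g0540400, 6.97, SE 0.63, n = 2, floored 6.36) on the higher side and a TGB12K interacting protein gene (Os08g0539600, -11.78, SE 0.72, n = 2, floored -10.74) on the lower side, dim on 3 of the 4 arrays of its lower side. The median of all probes was -0.18 here.

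**Figure D2:**
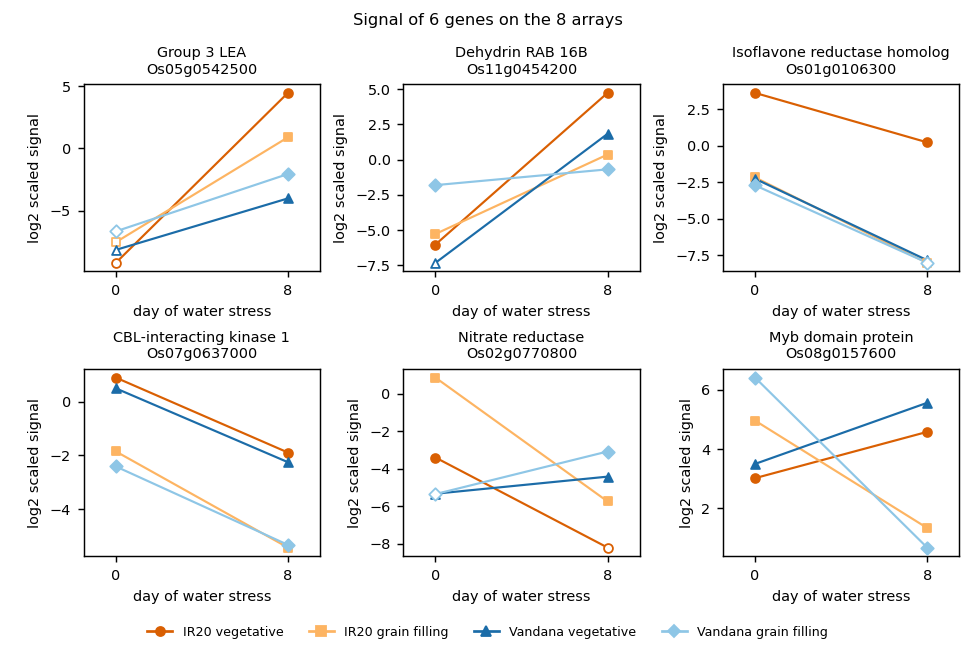
Log2 signal of 6 genes on each of the 8 arrays, scaled to the 75th percentile of the array, against the day of water stress. Each line joins the 2 arrays of a pair, and open symbols are not well above background. The LEA gene differs by 4.14 to 13.66 in the 4 pairs, the isoflavone reductase homolog by -5.84 to -3.38, and the Myb domain gene by 1.56 and 2.05 in vegetative leaves and by -3.62 and -5.73 at grain filling.

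**Figure D3:**
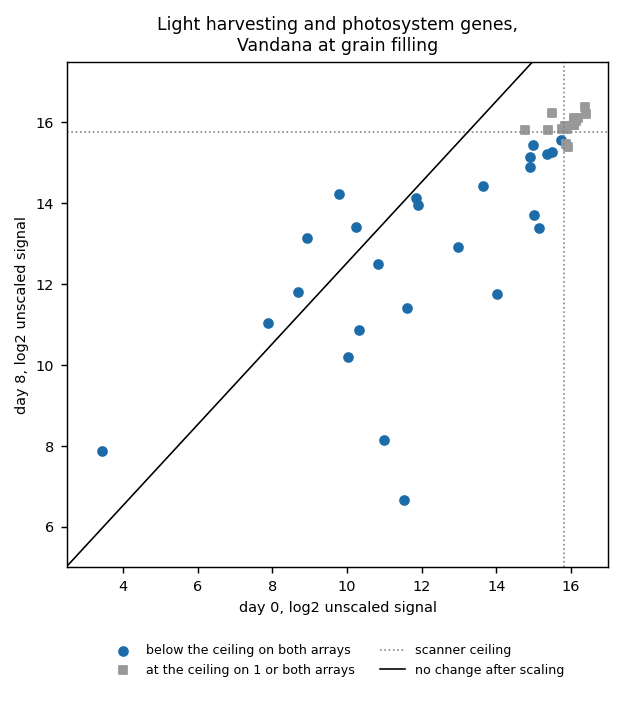
Unscaled log2 signal of the 45 light harvesting and photosystem genes on the Vandana grain-filling arrays of day 0 and day 8, with the scanner ceiling of each array (15.80 and 15.77) as dotted lines. Points below the solid line have a lower scaled signal at day 8. The 25 genes below the ceiling on both arrays had a median scaled difference of -2.28.

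The fourth question is how the varieties differed, with the matched stages and days as replicates. By camera with a preset correlation, lists of defence, wall and dehydration genes were called lower in Vandana than in IR20 and the clock list higher (adjusted p = 0.845 with an estimated correlation). The light harvesting and Calvin cycle lists were called higher in the same test (also adjusted p = 0.845 with an estimated correlation), but 30 of 45 and 10 of 10 of their genes reached the scanner ceiling on 1 or more arrays. The median was -0.92 for cell wall expansion, -0.67 for jasmonate synthesis and response, -0.52 for pathogenesis-related proteins, -0.90 for LEA proteins and dehydrins and -0.99 for compatible solute synthesis. It was 0.88 for light harvesting and photosystems, 0.95 for the Calvin cycle and 0.95 for the circadian clock. In the order vegetative day 0, vegetative day 8, grain filling day 0 and grain filling day 8, the medians were -2.75, -1.22, 0.61 and -0.02 for the cell wall, -1.21, -1.65, 0.61 and 0.23 for compatible solutes and -0.25, -3.89, 0.33 and -0.86 for LEA. They were -1.11, -1.23, -0.76 and 0.40 for jasmonate and 0.92, 1.44, 1.21 and 0.02 for the clock, and ran from -1.01 to 0.01 for pathogenesis-related proteins. They were 0.31, 0.77, 1.79 and 0.48 for light harvesting and 0.37, 0.77, 2.30 and 0.37 for the Calvin cycle. The value of 2.30 was at grain filling on day 0, where the log2 75th percentiles of the arrays were 10.62 in IR20 and 8.25 in Vandana, so a difference between the varieties cannot be read from the Calvin cycle list. Some of these signs turned with the scaling. LEA on vegetative day 0 was 0.28 under normexp and 0.10 under median centring, and at grain filling on day 0 -0.56 under quantile normalization. The cell wall list under normexp was 0.05 on vegetative day 8 and 0.31 at grain filling on day 8 (0.05 under median centring), and the pathogenesis-related list was 0.31 on vegetative day 8 and 1.14 at grain filling on day 0. Floored, the cell wall list was 0.23 at grain filling on day 8 and the pathogenesis-related list 0.32 on day 0. Under quantile normalization light harvesting was -0.02 on vegetative day 8 and the Calvin cycle -0.04 at grain filling on day 8. Under normexp background correction the pathogenesis-related median flipped to 0.20 and those of the cell wall and compatible solutes were -0.30 and -0.05, and under quantile normalization light harvesting was at 0.09 and the Calvin cycle at 0.10. Lipoxygenases Os12g0559200 (-6.25, SE 1.61, n = 4, floored -5.74) and Os12g0560200 (-6.15, SE 1.33, n = 4), the alpha-expansin OsEXPA5 (Os02g0744200, -4.29, SE 1.23, n = 4) and the LEA group 1 gene Os04g0589800 (-4.33, SE 1.33, n = 4, floored -3.44) were lower in Vandana in all 4 comparisons.

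Adjusted over the list alone, 1 pathogenesis-related gene was lower, a Bowman-Birk proteinase inhibitor (Os01g0127600, -4.01, SE 0.53, n = 4), against 0 over all genes, and in the other 7 called lists 0 passed over the list alone. At an unadjusted p under 0.05 the higher and lower members numbered 0 and 2 for LEA, 0 and 2 for compatible solutes, 1 and 6 for the cell wall, 0 and 2 for jasmonate, 5 and 0 for light harvesting, 1 and 0 for the Calvin cycle and 3 and 0 for the clock. Camera gave adjusted p values of 3.9e-05 for the cell wall, 5.06e-05 for light harvesting, 0.000563 for the Calvin cycle and for pathogenesis-related proteins, 0.00197 for jasmonate, 0.00274 for the clock, 0.0048 for LEA and 0.0224 for compatible solutes, and adjusted p = 0.845 with an estimated correlation for all 8. Under quantile normalization the camera direction of the light harvesting list turned (adjusted p = 0.998) while its median stayed positive at 0.09, and the Calvin cycle (0.803) and compatible solute (0.0531) calls ended. The 15 light harvesting genes below the scanner ceiling gave 0.712 (median 0.18). Without the vegetative arrays of day 8 LEA had 0.388 (median 0.06, so its sign turned) and compatible solutes 0.133 (median -0.37), without those of day 0 compatible solutes had 0.191 (median -0.59), and without the grain-filling arrays of day 0 jasmonate had 0.11 (median -0.28). The last also moved the medians of LEA to -1.75, of light harvesting to 0.53 and of the Calvin cycle to 0.51. The cell wall median was -0.61, -1.41 and -1.42 without the vegetative arrays of day 0, the grain-filling arrays of day 0 and those of day 8, and without the last the jasmonate median was -1.09.

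Over all genes limma called 0 of 34211 probes for variety (smallest adjusted p = 0.0525), with 2775 at an unadjusted p under 0.05 (1632 higher, 1143 lower), and a linear model without moderation called 0. Under normexp background correction 5163 were higher and 562 lower, and without the grain-filling arrays of day 0 the balance turned to 1271 higher and 2107 lower. The count was 1460 without the vegetative arrays of day 0 and 1192 without those of day 8. Under quantile normalization 3 probes passed, under median centring 7 and in an additive fit 11. The smallest p values belonged to an En/Spm-like transposon gene (Os10g0195100, 7.26, SE 0.38, n = 4, at least 75.5-fold higher in Vandana) and a protein phosphatase 2C-like gene (Os02g0599700, 6.85, SE 0.39, n = 4, at least 49.6-fold). They were followed, lower in Vandana, by a C2H2 zinc finger gene (Os09g0560900, -7.68, SE 0.54, n = 4, at least 76.1-fold lower) and a mitochondrial protein-like gene (Os12g0467700, -4.75, SE 0.37, n = 4, floored -3.29), whose other probe differed by only -0.32. Next was a Myb domain gene, higher in Vandana (Os07g0137000, 7.76, SE 0.61, n = 4, at least 94.2-fold). The phosphatase gene and 2 others of its list, Os02g0599100 (-4.37, SE 0.65, n = 4, floored -2.97) and Os02g0599200 (-5.53, SE 0.83, n = 4, floored -4.26), passed adjusted over the list alone, and floored these last calls ended (adjusted p = 0.0905). Chalcone synthase (Os07g0526400), the first enzyme of flavonoid synthesis, differed by -5.22 (SE 0.69, n = 4, floored -4.47) and an alcohol dehydrogenase (Os03g0189600) by -3.58 (SE 0.44, n = 4). An NBS-LRR-like gene (Os11g0674500), of the class of disease resistance receptors, differed by 3.39 (SE 0.55, n = 4). By 2-fold or more in all 4 comparisons, 188 genes were higher and 140 lower in Vandana, while by any amount 12.9% and 5.5% of all genes were. Slide and variety largely coincide: 3 of the 4 IR20 arrays share a slide, and no Vandana array was on it. A fit with slide as a block compares the varieties only on slide 2, where 1 IR20 array meets both Vandana vegetative arrays. That IR20 array is of grain filling on day 8, so its stage is corrected by the IR20 arrays of slide 1. This fit therefore cannot tell slide from variety over the 4 comparisons. The additive fit without slide gave 1238 higher and 1233 lower at an unadjusted p under 0.05.

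The fifth question is how leaves at grain filling differed from vegetative leaves. The lists of ABA synthesis and turnover (median -0.73, 7 genes), drought-associated transcription factors (-0.80, 15 genes) and heat shock proteins (-0.13, 127 genes) were called lower at grain filling by camera with a preset correlation (adjusted p = 0.978 with an estimated correlation). In the order IR20 day 0, IR20 day 8, Vandana day 0 and Vandana day 8 the medians were 1.94, -2.24, 0.08 and -2.57 for ABA synthesis and turnover, 0.49, -1.19, -2.58 and -0.35 for drought factors and 0.26, -0.39, -0.07 and -0.26 for heat shock. For ABA synthesis and turnover the Vandana day 0 value turned to -0.28, -0.08 and -0.01 under normexp, quantile normalization and median centring. For drought factors IR20 day 0 turned to -0.02 and Vandana day 8 to 0.56 under quantile normalization, and for heat shock Vandana day 0 turned to 0.23 under normexp. A 9-cis-epoxycarotenoid dioxygenase gene (Os03g0645900), of the enzyme class that makes the ABA precursor xanthoxin, differed by -2.27 (SE 0.59, n = 4), an ABA responsive element-binding factor (Os02g0766700) by -2.15 (SE 0.62, n = 4) and the small heat shock protein gene Oshsp17.3 (Os03g0266900) by -3.55 (SE 1.32, n = 4). A MADS-box gene of the flowering list (Os03g0752800) was higher by 6.98 (SE 1.51, n = 4) in 4 of 4 comparisons and passed adjusted over the list alone. Its limma adjusted p over the list was 0.0356, and the list itself did not pass (median 0.66, camera adjusted p = 0.0767). The seed storage list had a median of -0.54 (adjusted p = 0.939), and median, mean and test differed in sign for 7 lists that did not pass.

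Camera gave adjusted p values of 0.00362 for drought-associated factors and 0.0407 each for ABA synthesis and turnover and heat shock proteins, and adjusted p = 0.978 with an estimated correlation for each. In these lists 0 members passed over all genes or over the list alone with limma, and at an unadjusted p under 0.05 the higher and lower members numbered 0 and 1 for ABA, 0 and 2 for drought factors and 1 and 7 for heat shock. With the test restricted to genes below the scanner ceiling all 3 calls ended (adjusted p of 0.0629, 0.0629 and 0.0805 for ABA, drought factors and heat shock), although no ABA gene reached the ceiling and the median of that list stayed at -0.73. Those of the 8 drought factors and 119 heat shock genes left were -0.78 and -0.10, and quantile normalization gave 0.0583 for ABA and heat shock. Without the Vandana arrays of day 0 the adjusted p was 0.235, 0.345 and 0.285 (median -1.14 for ABA and -0.42 for drought factors), and without those of day 8 it was 0.181 for ABA (median -0.06) and 0.117 for heat shock (-0.03). Without the IR20 arrays of day 8 it was 0.0991 for ABA (median -0.23) and the heat shock median was -0.06, and without those of day 0 the ABA median was -1.62. Over all genes limma called 0 probes (smallest adjusted p = 0.658), with 1644 at an unadjusted p under 0.05 (1167 higher, 477 lower) where 1711 are expected, and a linear model without moderation called 0. In Vandana, stage and slide coincide: both vegetative arrays were on slide 2 and both grain-filling arrays on slide 3. The IR20 arrays of day 8 also lay on different slides. A fit with slide as a fixed block takes stage only from slide 1, where 1 grain-filling array (IR20 day 0) meets the IR20 vegetative arrays. It therefore cannot correct the stage difference of the 4 comparisons for slide. The additive fit without slide gave 1457 higher and 611 lower at an unadjusted p under 0.05. Without the Vandana arrays of day 0 1027 were higher and 1460 lower, so the balance turned. Without the IR20 arrays of day 8 the count was 758. By 2-fold or more in all 4 comparisons, 191 genes were higher and 59 lower, while by any amount 9.1% and 3.4% of all genes were. Among the named values, a peroxidase gene (Os07g0677400) differed by 4.77 (SE 0.72, n = 4) and a flavin-containing monooxygenase gene (Os04g0223500) by 4.05 (SE 0.64, n = 4). A RAP2.8 AP2 domain gene (Os01g0141000) differed by -4.50 (SE 0.44, n = 4, at least 11.2-fold lower), a clock coupling factor gene (Os01g0802600) by -5.21 (SE 0.78, n = 4) and an allantoin permease gene (Os12g0503000), a carrier of nitrogen-rich ureides, by -4.58 (SE 0.64, n = 4).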

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

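The tests against the scanner ceiling, the seed storage test at grain filling, the limit of the other seed test and of the LEA compression test to 1 pair, the values with dim signals raised to a floor, the list medians of single pairs under other scalings and the counts over other assignments of the samples were chosen only after the results were seen.

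In the Vandana grain-filling pair the median of the 45 light harvesting and photosystem genes was -2.53 at day 8, at percentile 0.0 of random lists matched on signal, and the day 0 array of this pair was the dimmest, with a log2 75th percentile of 8.25 against 10.22 to 11.46 on the other 7, and a spike-in slope of 0.837, against 0.882 at day 8 and 0.955 to 1.009 on the other 6. Under quantile normalization, which gives all arrays the same brightest values, the median was -0.13, so its size depends on the scaling. The 25 genes below the scanner ceiling on both arrays had a median of -2.28, at percentile 0.0 of random lists of equal signal. The 29 genes below it at day 0 had a median of -1.98 (day 8 values at the ceiling counted as highest, percentile 0.0). The smaller slope at day 0 would set bright genes lower there, not higher. However, the 15 genes below the ceiling on all 8 arrays had a median of -0.87 at percentile 3.1, inside the middle range of random lists. Some of the 25 genes also lay just under the ceiling on both arrays, such as Os09g0346500 (log2 15.73 and 15.57). These values therefore exclude neither compression of bright genes nor the ceiling for this list. For the 16 genes at the ceiling at day 0 the unscaled difference was -0.09 and the scaled one -2.62, so a change cannot be told apart from the scaling difference of -2.53, since their true signal is not measured. Leaves taken at another time of day cannot be told apart from stress either, and the labels give no hour of collection. The morning clock gene Os08g0157600 differed by -5.73 and the evening clock gene Os02g0618200 by 0.72, short of 2-fold. In IR20 at grain filling they differed by -3.62 and 2.03, past 2-fold in opposite directions, as another time of day would give. In vegetative leaves they differed by 1.56 and -0.63 in IR20 and by 2.05 and 1.79 in Vandana. A response of photosynthesis genes to stress at grain filling stays open, as untested.

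LEA and dehydrin genes were higher at day 8 (under normexp background correction their medians turned to -0.11 and -0.71 in the grain-filling pairs of IR20 and Vandana, and with dim values raised to the floor of their array to -0.09 in Vandana vegetative leaves) and more so in IR20, a difference by variety at a camera adjusted p of 8.63e-05 (medians -2.94 and -2.19), with 0.995 under an estimated correlation and 0.141 and 0.0673 without the IR20 or the Vandana vegetative pair. Many of these proteins are also abundant in seeds, but RNA of seed tissue is argued against in the IR20 vegetative pair, where the seed storage list (9 of its 34 genes pass the filter in these leaves, 0 shared with another list) stood at percentile 23.8 and its genes with the highest mean signal, Os05g0116000 and Os03g0188500, differed by -0.53 and -1.33. At grain filling it cannot be told apart from a stress response: the medians of the seed list were 0.38 in IR20 and 0.22 in Vandana (percentiles 80.5 and 92.4) with members going both ways, while the glutelin gene Os12g0283400 differed by 4.26 and 6.08, against -1.59 and -0.29 in vegetative leaves, a difference of 6.11 (5.23 with dim values raised, limma adjusted p over the list alone 0.0242 and 0.0177). Compression between arrays is argued against in the IR20 vegetative pair by the LEA list's percentile of 100 among lists of equal signal, and in IR20 at grain filling, Vandana vegetative leaves and Vandana at grain filling the percentiles were 100, 89.0 and 98.9. How dry the soil or leaves of each pair became is not in the labels, so a difference in the stress reached and a difference between the varieties both stay open, as untested.

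For the stress response, the real assignment of days gave 3653 probes at an unadjusted p under 0.05 and the highest of the other assignments, with 1 pair turned, 2830 (1 of 8 as large), and 8 assignments are too few for a share under 0.05.

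Between the varieties, 188 genes were higher and 140 lower by 2-fold or more in all 4 comparisons. Probes that bind poorly to 1 variety's sequence would give such differences, and of the other probes of these genes 84 of 93 (90.3%) differed by 2-fold or more the same way, against 93.2% for the stress response. Only 60 of the 328 genes (18.3%) have other probes, so the check is void for the set, and for the 268 genes with 1 probe sequence and expression cannot be told apart. Os12g0467700 shows the limit, with -4.75 on its probe of record and -0.32 on its other probe. The real assignment of varieties gave 2775 probes at an unadjusted p under 0.05 and the highest other 3164, with 1 pair turned (3 of 8 as large), the real assignment of stages gave 1644 and the highest other 3324, which follows the product of variety and stage (6 of 8 as large), and 8 are too few for a share under 0.05.

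Of 326 groups of values examined for 1 value far from the rest, 16 had one, and chance gives about 1 in 20, that is 16.3. For the stress response, the median of protein phosphatases 2C was -0.23 in IR20 at grain filling, against 0.01 to 0.05 in the other pairs. Os06g0274200 differed by 1.61 in Vandana vegetative leaves, against 3.11 to 3.28. Os10g0389200, red chlorophyll catabolite reductase, differed by -2.99 in the same pair, against 1.78 to 2.49. Glutamine synthetase gene Os02g0735200 differed by -2.87 in Vandana at grain filling, against -0.74 to -0.31, and ribosomal protein gene Os02g0255200 by 5.74 there, against 0.47 to 1.34. The glutelin family gene Os01g0607000 differed by -9.26 in IR20 vegetative leaves, against 0.51 to 1.41.

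Between the varieties, the median of antioxidant enzymes was 0.53 in vegetative leaves of day 0, against -0.06 to -0.01, and that of nitrogen assimilation was -0.17 at grain filling on day 8, against 0.83 to 1.02. At grain filling on day 0, Os07g0642100 differed by -3.60, against -5.30 to -5.19, and OsNAC6 (Os03g0815100, saturated on some arrays) by -2.89, against 0.42 to 0.87. Aquaporin TIP2.1 (Os02g0658100) differed by -3.56 at grain filling on day 8, against 0.25 to 0.97, and Os01g0607000 by -8.62 in vegetative leaves of day 0, against 0.74 to 2.05. Between stages, Os03g0322900 differed by -11.72 in IR20 on day 8, against -0.76 to -0.32, protochlorophyllide reductase A (Os04g0678700, saturated on some arrays) by 5.05 in Vandana on day 0, against -0.79 to 0.10, and Os02g0255200 by 7.47 in Vandana on day 8, against 1.32 to 2.20.

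The stress response also differed between the varieties, by camera, for chlorophyll synthesis (adjusted p 0.0309, medians 1.69 and -0.30) and cell division (0.01, 0.86 and -0.33), both at adjusted p = 0.995 with an estimated correlation, and the chlorophyll direction turned without the Vandana vegetative pair (0.94). Between stages it differed for ABA synthesis and turnover (0.0201), aquaporins (0.0452, and 0.0583 with dim values raised to the floor), light harvesting (2.03e-08), the Calvin cycle (0.000394), chlorophyll synthesis (0.0184), nitrogen assimilation (0.0201), ribosomal proteins (0.000911) and the clock (0.00627), all lower at grain filling in both varieties except ribosomal proteins in IR20 under quantile normalization (0.24), and none with an estimated correlation (0.785). All 10 Calvin cycle and 30 of 45 light harvesting genes were at the scanner ceiling on some arrays, and the unscaled Calvin cycle medians of day 8 minus day 0 were -0.02, -0.07, -0.01 and -0.17 in the 4 pairs, so its scaled difference follows the scaling of the arrays.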

How the results depend on the processing

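The settings restricted to probes or genes below the scanner ceiling, the lists without exclusions, the medians by scaling and dim values raised to the floor of their array were chosen after seeing the data. The 0 called probes for stress, for stress by variety, for stress by stage and for stage stayed 0 under every alternative run for each, slide as a block being run only for stress, variety and stage, while the variety count was 3 under quantile normalization, 7 under median centring and 11 in the additive fit, and the cause was not tested. With normexp correction the probes 2-fold higher were 3744 in IR20 at grain filling and 2862 in Vandana at grain filling, and those 2-fold lower in Vandana vegetative leaves 2387, and the cause was not tested. Lists called were 5, 3, 8, 8 and 3 for stress, stress by variety, stress by stage, variety and stage, and 0 in all 5 with an estimated correlation, which widens the test by construction. The list tests were not run under normexp background correction, for which only list medians are given. Quantile normalization gave 3 for stress, 2 for stress by stage, 5 for variety and 1 for stage, and genes below the ceiling 4 for stress by stage and 0 for stage, and the cause was not tested (the ABA list lost no gene). Dim values raised to the floor gave 4, 4, 7, 8 and 3 lists and ended all 6 LEA calls over the list alone (adjusted p 0.0527 to 0.0725). Leaving out a pair gave 3 to 7 lists for stress, 2 to 8 for stress by variety, 6 to 8 for stress by stage, 6 to 9 for variety and 2 to 7 for stage. Among lists past the threshold in the main or the other setting, the camera direction turned for light harvesting below the ceiling for stress (adjusted p 0.93). It also turned for light harvesting under quantile normalization for variety (0.998). Among such lists, leaving out a pair turned 7 directions, with these lowest and highest adjusted p. For chlorophyll synthesis, stress response by variety they were 5.83e-05 and 0.94 (turned without the Vandana vegetative pair). Without the Vandana grain-filling pair light harvesting and photosystems, stress response by variety turned at 0.000112 (highest 0.458), Calvin cycle, stress response by variety at 0.0197 (0.00292 to 0.929), cytosolic ribosomal proteins, stress response by variety at 0.0031 (highest 0.929) and drought-associated transcription factors, stress response by stage at 0.023 (0.0184 to 0.703). LEA proteins and dehydrins, stage difference turned at 0.0146 without IR20 day 8 (highest 0.816) and cytosolic ribosomal proteins, stage difference at 0.00011 without Vandana day 8 (highest 0.963). The cause was not tested. The other list results numbered 1155 alike, 39 newly past and 84 no longer past the threshold. In 133 more the camera direction turned with the list past the threshold in neither setting. Of the named genes' values 5895 were alike, 180 shifted and 7 newly passed (variety). In the fits, shifted means that the sign turned with no call in either setting. Within single pairs it means a change of over 2-fold with the sign kept. No value that passed in either setting turned direction. Signal over background limits genes whose lower side is at background. Their differences depend on the background of the array, and a least fold is given for only some of them. The ceiling limits the brightest genes.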

Other observations

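Only the values with dim signals raised to the floor of their array, called floored, were added after seeing the data. The genes in this paragraph belong to lists that did not pass for the stress response, and none of their values passed over all genes. The protein phosphatase 2C gene Os05g0572700, of a family that restrains ABA signalling, differed by 4.61 (SE 0.96, n = 4, floored 3.59), with 4.30, 7.93, 4.06 and 2.15 in the IR20 vegetative, IR20 grain-filling, Vandana vegetative and Vandana grain-filling pairs. The protein kinase gene Os12g0586100 differed by 2.82 (SE 0.80, n = 4), higher in 4 of 4 pairs. Its response was higher at grain filling by 3.32 (SE 0.69, n = 2), which passed limma adjusted over the list alone. The raffinose synthase gene Os07g0209100 differed by 3.20 (SE 0.94, n = 4) and the sucrose synthase gene Os04g0309600 by -2.06 (SE 0.43, n = 4), each the same way in all 4 pairs. A histone H3 gene (Os04g0419600) differed by -2.28 (SE 0.33, n = 4, floored -1.52).

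Among flowering genes, which were tested as 1 list, the response to stress differed between stages for 3 of 7 members adjusted over the list alone, against 0 over all genes. They were the PEBP family gene Os06g0157500 (-6.56, SE 1.27, n = 2), the photoperiod gene Hd1 (Os06g0275000, 3.43, SE 0.87, n = 2) and Os10g0463400 (-3.33, SE 0.92, n = 2), while the list itself did not pass (median -1.02, camera adjusted p = 0.381). Floored, only the PEBP gene passed over the list alone (limma adjusted p of 0.0355, with 0.0508 for Hd1 and 0.0641 for Os10g0463400). In the 4 pairs the PEBP gene differed by -2.40, -6.64, 0.00 and -8.88 and Hd1 by 0.97, 3.16, -0.89 and 3.79. The Bowman-Birk inhibitor genes Os01g0127600 (-3.14, SE 0.54, n = 4) and Os01g0124400 (3.07, SE 0.85, n = 4) differed in opposite directions under stress in all 4 pairs.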
